A study of Homo sapiens with 6 samples.

How the data were processed

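RNA from 6 samples of HaCaT keratinocytes was profiled on Affymetrix arrays, 3 infected with a lentivirus for GJB2 G130V and 3 with an empty vector lentivirus. Per the labels' protocols, total RNA was extracted with Trizol and copied into biotin-labelled cRNA. The study's design text also mentions a second GJB2 mutant, which was not analysed here. Samples were grouped by their titles, which also number the replicates 1 to 3 in each group.

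The value table holds log2 expression per probe set as deposited, already normalized between arrays by the authors, with RMA and limma named per the submitters' processing notes, without versions or settings. That the values are log2 was checked on the file: the difference of group means equalled the deposited log2 change of the authors for all 39345 probe sets, to within 9.49e-15. A second deposited table carries the word filtered in its name, though it lists the same probe sets, and what the filter was is not given in the sources used here. It annotates the probe sets and gives the authors' own comparison of the groups, with a p-value and its FDR per probe set, a log2 change, a signed fold change in which falls are written as the negative inverse, and a fold change without sign. The authors' deposited table lists 13244 probe sets with an FDR under 0.05 (6719 higher and 6525 lower), 813 of them at least 1.5-fold and 102 at least 2-fold. Its p-values were matched by limma with a mean-variance trend on all probe sets, with a largest difference of 0.00125 in log10 p. That table also holds 6 columns of values per sample whose names match no sample label, and these were not used. The array design and the genome build of the annotation are not given in the sources used here, so coordinates are printed as that table lists them.

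Of the 39345 probe sets, 73 were controls, 37522 had 1 gene symbol, 1556 had several and 194 had none. Symbols were updated through Entrez Gene identifiers with a RefSeq gene table used for names only (assembly GRCh38.p14), which held the identifiers of 37447 probe sets and changed the symbol of 1869. Each gene was represented by its probe set with the highest mean over the 6 arrays, which left 15900 genes, 9682 of them with 2 or more probe sets. Probe sets with several symbols or none were left out of the gene comparison, and no filter on dim genes was applied. Names that end in _s_at or _x_at mark probe sets that can detect related transcripts too, which holds for 42 of the 104 genes named by the rule below. Of the 73 such genes with 2 or more probe sets, 67 had all of them moving in 1 direction, and GJB2, DST and MAP2 each had a probe set called in the opposite direction. The files used here hold no detection calls, and levels at the low end may be close to background.

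The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, group as the only term, 2-sided), with Benjamini-Hochberg adjustment over all genes and calls at an adjusted p under 0.05. GJB2 and FLG were also read per probe set from the same fit over the 37522 probe sets with 1 symbol. Changes are differences of group means, G130V minus empty vector, on the log2 scale, with standard errors and 95% confidence intervals from the moderated variances. The 27 gene lists were tested with limma's camera (preset inter-gene correlation 0.01, Benjamini-Hochberg over the lists, at least 5 measured genes), with the correlation estimated per list and with limma's fry as alternatives. Bootstrap intervals of list medians drew the members 10000 times. The lists covered connexins and pannexins, the cornified envelope, basal keratinocytes, stress keratins and alarmins, simple epithelial keratins, cell junctions, p53 targets, apoptosis regulators, the unfolded protein response, interferon-stimulated genes, NF-kB targets, S phase, G2 and M phases, cholesterol synthesis, mesenchymal and matrix genes, hypoxia and glycolysis, NRF2 targets, calcium handling, EGF ligands and AP-1, heat shock, replication-dependent histones, ribosomal proteins, and markers of fibroblasts, melanocytes, immune, endothelial and neural cells.

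The design, the lists and all alternatives except those listed last were set before the data were examined. So was the rule for the genes named, which were GJB2, LOR and FLG, other connexins and pannexins that passed, the 10 largest rises and 10 largest falls among genes that passed, did not overlap between the groups and had the higher group mean above the median of all group means (8.26), and up to 4 members per list with the smallest adjusted p, where they passed. Some genes that met the rule are not reported here. Genes named outside that rule are said to have been chosen after their values were seen. LOR had no probe set in the tables used and was not analysed here.

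The alternatives were the replicate number as a block, leaving out each array, filters on the dimmest 20% or 50% of genes, quantile normalization or median centring of the arrays, the mean of all probe sets of a gene or every probe set on its own, a variance prior with trend and robust, array weights, stricter thresholds, and camera on ranks. Those listed last, chosen after the data were seen, were a prior with trend alone, a shift of each array to equal means of the 24 poly-A spike probe sets, a list of YAP and TAZ targets and the Gene Ontology process terms of the annotated table. Terms with 15 to 200 measured genes were used, and the cells that could be used gave terms for 12054 genes, while for 1452 genes they were not used here.

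The fit was tested on simulated data for 15900 genes with the means and spreads of the arrays and 200 genes changed by known amounts. It recovered 62.7% of changes of 0.25 (log2), 98.5% of changes of 0.5 and 100% of changes of 1, with 13 false calls. Camera called the shifted list and 0 of 20 random lists. The simulated genes varied independently and camera ran at the preset correlation, so that result does not bear on lists whose genes vary together. The 200 changed genes were also far fewer than the 4772 called in the data. Precision is limited by the 3 arrays per group.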

Results

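Genome-wide transcript levels were measured in HaCaT cells, a spontaneously immortalized line of human epidermal keratinocytes, on 6 Affymetrix expression arrays. In 3 samples, by their titles, the cells had been infected with a lentivirus made to overexpress GJB2 carrying the G130V change, in which glycine 130 of the protein is replaced by valine. In the other 3 samples they had been infected with a lentivirus holding the empty GV308 vector. No sample was given GJB2 without the G130V change. GJB2 encodes connexin 26, a gap junction protein, and mutations in it cause deafness and skin disease. Each array gave log2 values for 39345 probe sets, with array medians between 7.87 and 7.91, and 15900 genes were compared. Arrays of the same group correlated with Pearson's r between 0.998 and 0.999 and arrays of different groups with r between 0.992 and 0.994, and the first principal component, which separated the groups, held 69.4% of the variance. RNA integrity, read from the difference between 3′ and 5′ control probe sets, was alike in both groups, with shifts of 0.0023 for beta-actin and -0.0018 for GAPDH (log2). The 24 probe sets for poly-A transcripts that are spiked into the RNA before labelling read 0.31 higher (log2) in the G130V group, at 8.90 ± 0.0070 against 8.59 ± 0.071 (SD, n = 3 each), with an exact 2-sided permutation p of 0.1, the smallest that 3 arrays against 3 allow. Changes below are therefore relative to the bulk of genes, whose median change was 0.0048 as deposited and -0.31 with the arrays shifted to equal poly-A spikes, and since that shift is the same for every gene, any rise of less than 0.31 reads below 0 under it. The number of arrays limits the precision, and the labels do not say whether replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

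The first comparison asked whether GJB2 transcript was higher in the cells given the G130V virus. It was not raised on the probe set used for the gene: GJB2 (Entrez Gene 2706) fell by 0.35 on the log2 scale, a change of 1.28-fold, from 7.31 ± 0.099 with the empty vector to 6.96 ± 0.13 with G130V (SD, n = 3 each). The 3 GJB2 probe sets went different ways. The probe set aligned to a span of 681 bases, the length of the GJB2 coding sequence, read 0.14 higher, and those aligned to the longer transcript read -0.35 and -0.19. In the mean of the 3 GJB2 changed by -0.13 and lost its call (adjusted p = 0.0857). Other connexins moved by similar amounts: GJC1 (connexin 45) fell by 0.29 and GJA1 (connexin 43, the most widely expressed family member) fell by 0.20.

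All 3 GJB2 probe sets lie on chromosome 13 in the annotation of the deposited table, whose genome build is not named in the file. Probe sets 11727085_s_at and 11727084_at were aligned from position 20761605 to 20767149 and 11748025_s_at from 20763040 to 20763720. For 11727085_s_at the limma fit over all probe sets gave a standard error of 0.075 and an adjusted p of 0.00955, with a 95% confidence interval of the change from -0.53 to -0.18. Probe set 11727084_at, at 6.42 ± 0.19 with the empty vector and 6.22 ± 0.099 with G130V, did not pass (SE 0.096, adjusted p = 0.179), although without empty vector replicate 1 it read -0.30 with an adjusted p of 0.0189. The coding sequence probe set 11748025_s_at read 6.85 ± 0.061 with the empty vector and 6.99 ± 0.017 with G130V (SD, n = 3 each), a change of 1.10-fold with a confidence interval from 0.04 to 0.25 and an adjusted p of 0.0462 in the same limma fit. That call was lost on leaving out any array other than empty vector replicate 1, with adjusted p from 0.0766 to 0.141 over those 5 fits, while the change stayed between 0.11 and 0.17 over all 6. It was also lost with median centring, with quantile normalization and with a variance prior with trend, robust or not (adjusted p from 0.0560 to 0.118). The value also turned to -0.17 with the arrays shifted to equal poly-A spikes. The 3 probe sets were dim, at the 21.2 to 36.2 percentiles of all probe sets, where values may lie close to background, and the files used here carry no detection calls.

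**Figure D1:**
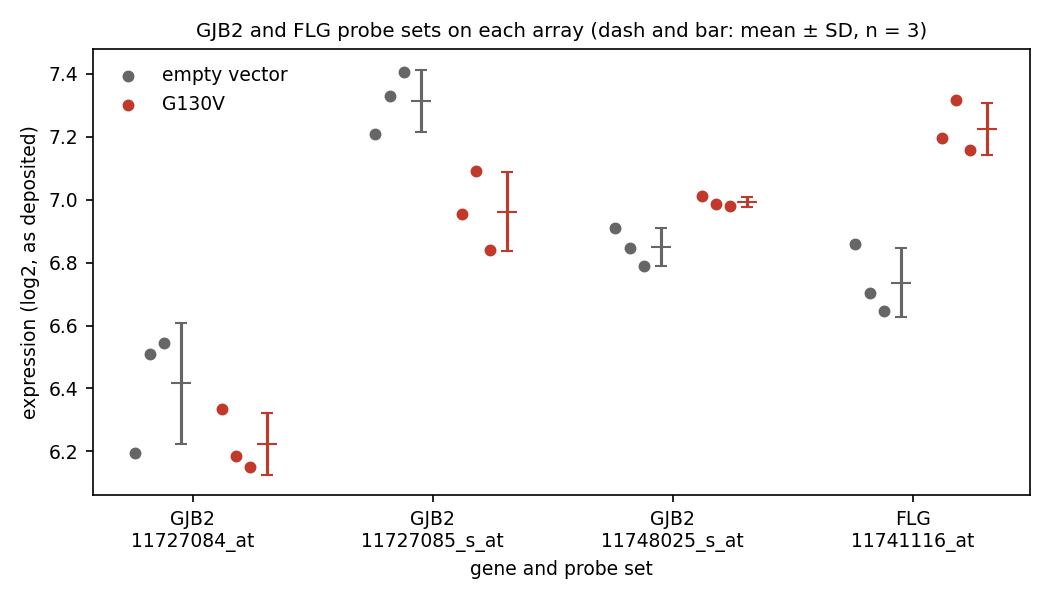
Expression (log2, as deposited) of the 3 GJB2 probe sets and the FLG probe set on each of the 6 arrays, empty vector in grey and G130V in red, with the mean and SD of each group beside the points. On 11727085_s_at the G130V arrays lie between 6.84 and 7.09 and the empty vector arrays between 7.21 and 7.40, and on the FLG probe set the G130V arrays lie above all empty vector arrays.

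FLG and LOR, which encode the epidermal proteins filaggrin and loricrin, are the transcripts that the study's design names as readouts of keratinocyte differentiation. FLG rose 1.40-fold in G130V cells, from 6.74 ± 0.11 to 7.22 ± 0.083 (log2, SD, n = 3 each), and every G130V array lay above every empty vector array. The change was 0.49 with a standard error of 0.067 and an adjusted p of 0.00125 over all genes (limma). Its probe set 11741116_at (Entrez Gene 2312) is annotated to chromosome 1, positions 152274638 to 152287955, in the same unnamed build. The FLG level was also low, at the 33.3 percentile of all probe sets, and its call was lost with the arrays shifted to equal poly-A spikes, where the change was 0.18 with an adjusted p of 0.0960. LOR was not analysed here, since no probe set in the tables used carries its symbol.

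FLG belongs to a list of cornified envelope and late differentiation genes that were fixed before the data were examined, and that list moved in both directions. Of its 33 measured members 8 rose, 2 fell and 23 did not pass. CSTA, which encodes the protease inhibitor cystatin A, rose by 0.55, SPINK5, encoding the epidermal protease inhibitor LEKTI, by 0.63 and KLK7, a protease of the outer epidermis, by 0.45. SCEL, encoding the envelope precursor sciellin, fell by 0.27. The counts were 9 and 4 when adjusted over the list alone. The median was 0.0047 (95% bootstrap interval -0.036 to 0.038), against -0.31 at equal poly-A spikes, where 4 rose and 23 fell, and camera gave no call (adjusted p = 0.431).

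The main comparison asked which genes differ between G130V and empty vector cells. Genes of DNA replication (31 of 33) and of mitosis (37 of 37) fell in the G130V cells, while genes induced by interferon (27 of 37), by low oxygen (25 of 29) and by protein misfolding in the endoplasmic reticulum (19 of 28) rose. These 5 lists were called by camera at a preset correlation and not with an estimated correlation (adjusted p from 0.0998 to 0.123). At equal poly-A spikes the rises came to 17, 12 and 11, beside 10, 6 and 9 falls. Broader Gene Ontology terms, chosen after the data were seen, had smaller medians. Of 85 genes of the response to hypoxia 29 rose and 5 fell (median 0.043). Among 81 genes of defense against virus 29 rose and 10 fell (median 0.041). For the unfolded protein response 24 of 73 rose and 8 fell (median 0.084). In the smaller term of type I interferon signalling 19 of 33 rose and 0 fell (median 0.21). The largest fall was that of RFLNB, whose product refilin B organizes actin filaments, which dropped by 2.16 on the log2 scale (4.46-fold), and the largest rise was that of AGR2, a protein disulfide isomerase of the endoplasmic reticulum, at 1.66 (3.17-fold). NDRG1 rose by 1.53 and EGLN3 by 1.51, both classical targets of the hypoxia-inducible factors. NRG1, which encodes the receptor ligand neuregulin 1, fell by 1.59 and RRM2, a subunit of ribonucleotide reductase, fell by 1.30.

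In the limma fit 4772 of 15900 genes passed an adjusted p of 0.05. Of these 2548 rose and 2224 fell. Most changes were small. The median size among called genes was 0.25 (log2), and 328 called genes changed at least 1.5-fold (166 rose, 162 fell) and 44 at least 2-fold (25 rose, 19 fell). The groups did not overlap at 7078 genes, or 44.5%, where chance gives 10%. At equal poly-A spikes 352 genes rose and 13084 fell, so that 2.62% of the calls were rises, against 53.4% with the values as deposited. That shift cost KRT5, KRT6A, S100A7, S100A8, PKP1, SESN1, TRADD, TM7SF2, STIM2, H2BC12 and HLA-DRA, all named below, the call of their rise.

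The 10 largest rises among genes that met the naming rule ran from 1.20 to 1.66 (log2). AGR2 went from 8.95 ± 0.069 to 10.6 ± 0.062 (SD, n = 3 each), with an adjusted p of 5.71e-06. After NDRG1 (SE 0.041, adjusted p = 4.04e-06) and EGLN3, a prolyl hydroxylase that marks hypoxia-inducible factors (SE 0.079, adjusted p = 2.12e-05), came SELENOP, the selenium carrier selenoprotein P, at 1.39, and VAV3 at 1.36. MXRA5, a matrix remodelling protein, rose by 1.29, TMT1A, a thiol methyltransferase, by 1.26, RSAD2, the interferon-induced antiviral protein viperin, by 1.25, RGS2, a regulator of G protein signalling, by 1.21 and TPRG1 by 1.20.

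The 10 largest falls ran from -1.06 to -2.16. RFLNB went from 8.65 ± 0.055 to 6.49 ± 0.041 (SD, n = 3 each), with an adjusted p of 1.03e-06, and NRG1 from 11.5 ± 0.061 to 9.96 ± 0.045, with an adjusted p of 5.16e-06. CALD1, encoding the actin-binding protein caldesmon, fell by 1.25, MYBL1, a transcription factor, fell by 1.20, INHBA, the activin A subunit, fell by 1.19 and IFFO2 fell by 1.17. TGFB2, the growth factor TGF-beta 2, fell by 1.11, AREG, the EGF receptor ligand amphiregulin, fell by 1.09 and GINS2, part of the replicative helicase, fell by 1.06.

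**Figure D2:**
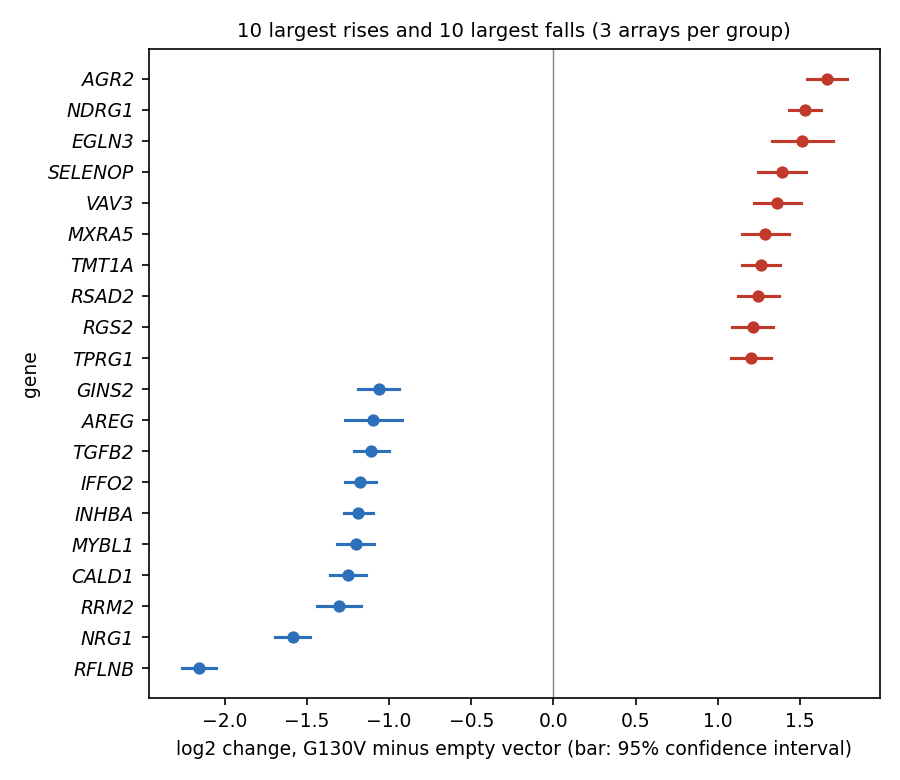
Log2 change (G130V minus empty vector) of the 10 genes with the largest rise (red) and the 10 with the largest fall (blue) under the naming rule, with bars for the 95% confidence interval from limma, 3 arrays per group. The interval of RFLNB, from -2.26 to -2.05, lies below all others, and that of AGR2 runs from 1.54 to 1.78.

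Gene lists fixed before the data were examined described which functions moved. Of 27 lists tested with limma's camera at a preset inter-gene correlation of 0.01, 12 were called, 6 upward and 6 downward. None of the 27 was called with the correlation estimated from the data, where the lowest adjusted p was 0.0998 and 7 lists had an unadjusted p under 0.05. limma's fry, which asks whether a list's genes move on balance in one direction, called 24.

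Proliferation genes fell. All 37 measured genes of the G2 and M phases fell, with a median of -0.44 (95% bootstrap interval -0.52 to -0.39). CDCA3, which triggers mitotic entry, fell by 0.94, ANLN, which encodes the cytokinesis protein anillin, fell by 0.71, CCNA2 (cyclin A2) fell by 0.67 and AURKA (Aurora kinase A) fell by 0.57. Of 33 genes of S phase, 31 fell and 1 rose, with a median of -0.55 (interval -0.68 to -0.38). UHRF1, which maintains DNA methylation, fell by 0.98, CDCA7 fell by 1.01 and TYMS, encoding thymidylate synthase, fell by 0.88. The member that rose was CCNE1, cyclin E1, at 0.39, which was chosen after its value was seen. The falls numbered 37 of 37 and 32 of 33 adjusted over the list alone. Camera gave adjusted p = 7.07e-24 for G2 and M and 1.96e-20 for S phase, against adjusted p = 0.101 and adjusted p = 0.0998 with an estimated correlation.

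Probe sets of replication-dependent histone genes read the other way from those of the cell cycle genes. These values do not tell which forms of the histone transcripts were read, so they do not show that histone expression of S phase rose. Of 9 measured, 6 rose and 3 did not pass, with a median of 0.35 (interval 0.041 to 0.73). H2BC5 rose by 0.92, H2AC6 by 0.73, H2BC21 by 0.58 and H2BC12 by 0.35, and 6 rose when adjusted over the list alone. At equal poly-A spikes 3 members rose, 2 fell and the median was 0.042. The list was called upward (camera adjusted p = 8.89e-04, and adjusted p = 0.123 with an estimated correlation).

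Interferon-stimulated genes rose. Of 37 measured members 27 rose and 10 did not pass, with a median of 0.42 (interval 0.27 to 0.54), or 1.33-fold. Beside RSAD2, OASL, a member of the oligoadenylate synthetase family, rose by 1.19, HERC5, the ligase for ISG15, by 0.87 and IFIT1, which binds viral RNA, by 0.79. There were 29 rises and 1 fall adjusted over the list alone, and without empty vector replicate 1 there were 25 rises and 1 fall. At equal poly-A spikes 17 members rose, 10 fell and the median was 0.10. Camera gave an adjusted p of 3.51e-14, against adjusted p = 0.123 with an estimated correlation.

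Hypoxia and glycolysis genes rose alongside them. Of 29 members 25 rose and 1 fell, with a median of 0.40 (interval 0.25 to 0.50). Beside NDRG1 and EGLN3, the mitophagy receptor gene BNIP3 rose by 1.10 and ALDOC, a glycolytic aldolase, by 0.61. The member that fell was SLC2A1, the glucose transporter GLUT1, at -0.14, named after its value was seen, and its call was lost without empty vector replicate 2, empty vector replicate 3, G130V replicate 1 or G130V replicate 3. The counts adjusted over the list alone were 27 and 1, and at equal poly-A spikes 12 rose, 6 fell and the median was 0.083. Camera gave an adjusted p of 7.74e-14, against adjusted p = 0.123 with an estimated correlation.

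Genes of the unfolded protein response, which refold or degrade proteins of the endoplasmic reticulum, also rose. Of 28 members 19 rose and 2 fell, over all genes and adjusted over the list alone, with a median of 0.31 (interval 0.16 to 0.49). HERPUD1, which serves degradation from the endoplasmic reticulum, rose by 0.72, SDF2L1 by 0.65, MANF by 0.64 and the co-chaperone gene DNAJB9 by 0.59. The members that fell, named after their values were seen, were the stress transcription factor ATF3 at -0.42 and ASNS, asparagine synthetase, at -0.22. At equal poly-A spikes 11 members rose, 9 fell and the median lay at 6.31e-05. Camera gave an adjusted p of 3.01e-08, against adjusted p = 0.123 with an estimated correlation.

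Heat shock genes, most of which serve protein folding in the cytosol, fell. Of 19 members 12 fell and 1 rose, with a median of -0.23 (interval -0.35 to -0.13), against 19 falls and a median of -0.54 at equal poly-A spikes. CHORDC1 fell by 0.70, HSPA8, the constitutive HSP70, fell by 0.55, HSPH1 fell by 0.53 and AHSA1, an activator of HSP90, fell by 0.41. The member that rose was HSPB1, at 0.15, named after its value was seen. Its call was lost without empty vector replicate 2, empty vector replicate 3 or G130V replicate 1. When adjusted over the list alone 14 fell and 1 rose (camera adjusted p = 7.31e-06, and adjusted p = 0.315 with an estimated correlation).

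Targets of NRF2, the transcription factor of the oxidative stress response, fell as well. Of 28 members 19 fell and 1 rose, over all genes and adjusted over the list alone, with a median of -0.18 (interval -0.36 to -0.079). With the arrays shifted to equal poly-A spikes 28 fell and the median was -0.49. TXNRD1 (thioredoxin reductase) fell by 0.59, HMOX1 (heme oxygenase) fell by 0.52, NQO1 fell by 0.46 and SRXN1 (sulfiredoxin) fell by 0.42. The member that rose, SQSTM1 at 0.16, was named after its value was seen, and its call was lost without G130V replicate 1 or G130V replicate 3. Camera gave an adjusted p of 6.79e-07, against adjusted p = 0.238 with an estimated correlation.

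EGF family ligands and AP-1 and ERK target genes fell. Of 30 members 18 fell and 2 rose, with a median of -0.21 (interval -0.47 to -0.12), against 29 falls, 1 rise and a median of -0.52 at equal poly-A spikes. Beside NRG1, FOSL1, an AP-1 subunit, fell by 0.95, DUSP6, a phosphatase that ERK signalling induces, fell by 0.86 and EGR1, an immediate early gene, fell by 0.77. The members that rose, named after their values were seen, were FOS at 0.51 and FOSL2 at 0.14. A single member rose without empty vector replicate 2 or 3 and without G130V replicate 1 or 3. Adjusted over the list alone 19 fell and 2 rose (camera adjusted p = 5.08e-08, and adjusted p = 0.0998 with an estimated correlation).

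With the values as deposited, mesenchymal and matrix genes split into a group with large falls and a group near 0. Of 21 members 9 fell, 2 rose and 10 did not pass, against 20 falls and 0 rises at equal poly-A spikes, with a median of -0.40. Beside TGFB2, CCN1, a matricellular protein gene, fell by 0.88 and CDH2 (N-cadherin) fell by 0.61. The members that rose, named after their values were seen, were MMP2 at 0.19 and TGFBI at 0.14. A single member rose without any one of the empty vector arrays or without G130V replicate 1. The median was -0.087 (interval -0.64 to -0.011), and adjusted over the list alone 9 fell and 3 rose. Camera gave an adjusted p of 0.00332, against adjusted p = 0.238 with an estimated correlation and 0.0553 with the dimmer 50% of genes left out.

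Basal keratinocyte genes rose on balance. Of 19 members 12 rose and 5 fell, with a median of 0.17 (interval 0.044 to 0.23), against -0.14 at equal poly-A spikes, where 1 rose and 11 fell. The keratin genes KRT15 and KRT5 rose by 0.68 and 0.42. DST, which links keratin to hemidesmosomes, fell by 0.43, but only 3 of its 6 probe sets had that sign and 1 was called in the opposite direction. Without empty vector replicate 2 or 3 there were 3 falls. In counts adjusted over the list alone 13 rose and 5 fell. Camera gave an adjusted p of 0.0276, which was 0.0564 without G130V replicate 1, 0.0528 with the dimmer 50% of genes left out, and adjusted p = 0.550 with an estimated correlation.

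Junction, stress and simple keratin lists were not called by camera, though fry called each of them. Of 20 junction genes 7 rose and 3 fell. The desmosomal genes went both ways: DSC3 rose by 0.72, DSG3, the pemphigus vulgaris antigen, by 0.49, DSC2 by 0.44 and PKP1 by 0.41, while PKP2 fell by 0.18, a call lost without empty vector replicate 2, and DSP, DSG2, JUP and PKP3 did not pass. The other falls were those of TJP1 at -0.27 and CLDN7 at -0.25, and these and the desmosomal genes after PKP1 were named after their values were seen. The list's camera adjusted p of 0.105 became 0.0455 without G130V replicate 2 and 0.0465 with arrays quantile normalized again, and its median of 0.089 became -0.22 at equal poly-A spikes, where 3 rose and 13 fell. Of 14 stress keratin and alarmin genes 6 rose and 1 fell (camera adjusted p = 0.134): S100A7 rose by 0.39, KRT6A by 0.38, S100A8 by 0.38 and S100A9 by 0.25, the last at -0.064 at equal poly-A spikes. Their median of 0.067 became -0.25 under that shift, where 0 rose and 9 fell. KRT17 was the stress keratin that fell, at -0.15, named after its value was seen, and its call was lost without empty vector replicate 2 or 3 or without G130V replicate 1 or 3. Of 8 simple epithelial keratins 4 fell and 2 rose (camera adjusted p = 0.297), against 7 falls and 0 rises at equal poly-A spikes. KRT7 fell by 0.41, KRT80 fell by 0.27, KRT18 fell by 0.22 and KRT13 rose by 0.18, with a value of -0.13 at equal poly-A spikes. Adjusted over the list alone there were 8 rises and 3 falls among junction genes, 6 and 1 among stress genes, and 2 and 4 among simple keratins.

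The study's design also names apoptosis. Of 29 apoptosis regulators 8 rose, 4 fell and 17 did not pass, and camera did not call the list (adjusted p = 0.297), though fry did. The median was 0.051, against -0.26 at equal poly-A spikes, where 2 rose and 24 fell. TNFSF10, which encodes the death ligand TRAIL, rose by 0.87 and TRADD, an adaptor of TNF receptor signalling, by 0.41. CFLAR, an inhibitor of caspase 8, fell by 0.41 and BID, a proapoptotic BCL2 family member, fell by 0.36. Without empty vector replicate 2 there were 5 rises. The call of CFLAR, whose 8 probe sets were split 4 against 4 in sign, was lost in the mean of its probe sets, at -0.11 with an adjusted p of 0.0543. There were 8 rises and 6 falls adjusted over the list alone.

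Targets of p53 rose on balance. Of 24 members 15 rose and 4 fell, with a median of 0.18 (interval 0.077 to 0.28), against -0.13 at equal poly-A spikes, where 2 rose and 11 fell. TP53INP1 rose by 0.88, the antiproliferative gene BTG2 by 0.59 and SESN1 by 0.38, while GADD45A, a stress sensor that slows the cell cycle, fell by 0.61. There were 2 falls without empty vector replicate 1, empty vector replicate 2 or G130V replicate 3, and 1 without empty vector replicate 3 or G130V replicate 1. Adjusted over the list alone 16 rose and 4 fell (camera adjusted p = 2.16e-04, and adjusted p = 0.366 with an estimated correlation).

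Inflammatory genes split. Of 28 targets and mediators of NF-kB signalling 13 rose and 5 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.216). The chemokine gene CCL5 rose by 1.15, while PTGS2, encoding cyclooxygenase 2, fell by 0.97, IL1B fell by 0.81 and LIF fell by 0.64. Without empty vector replicate 3 there were 8 rises, and the median of 0.075 became -0.24 at equal poly-A spikes, where 4 rose and 16 fell. Of 24 cholesterol synthesis genes 6 rose and 6 fell, over all genes and adjusted over the list alone (median -0.023, against -0.34 at equal poly-A spikes, where 0 rose and 21 fell; camera adjusted p = 0.635). FDPS, farnesyl diphosphate synthase, fell by 0.35, ACAT2 fell by 0.24 and TM7SF2 rose by 0.32. The rises came to 3 without empty vector replicate 1 or 2 and to 2 without empty vector replicate 3, G130V replicate 1 or G130V replicate 3. Of 26 calcium handling genes 7 rose and 2 fell, over all genes and adjusted over the list alone (median 0.048, against -0.26 at equal poly-A spikes, where 2 rose and 18 fell; camera adjusted p = 0.431). PLCB1 rose by 0.59, the calcium channel gene TRPV4 by 0.44 and STIM2, a sensor of stored calcium, by 0.39, and PRKCA fell by 0.35.

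Among 13 connexins and pannexins 4 fell, 1 rose and 8 did not pass (median -0.070, against -0.38 at equal poly-A spikes, where 0 rose and 12 fell; camera adjusted p = 0.216). GJA1 had an adjusted p of 0.00540 and GJC1 of 0.00597 in the limma fit, and the call of GJA1 was lost in the mean of its probe sets (-0.10, adjusted p = 0.0664). No member rose without empty vector replicate 1 or 2 or without G130V replicate 1 or 3. Adjusted over the list alone 2 rose and 5 fell.

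Ribosomal protein genes stayed near 0. Of 49 members RPS9 alone passed, at 0.16, and its call was lost without empty vector replicate 1, empty vector replicate 2, G130V replicate 1 or G130V replicate 3, with adjusted p from 0.0505 to 0.0705. It turned to -0.16 at equal poly-A spikes. Their median was 0.012 (-0.30 at equal poly-A spikes, where all 49 fell; camera adjusted p = 0.407), and none passed adjusted over the list alone, where 3 rose at an unadjusted p under 0.05 (limma).

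Markers of other cell types gave no list call with camera, though fry called the melanocyte, immune and endothelial lists. Of 10 fibroblast markers 1 rose (DCN, 0.25; camera adjusted p = 0.635), of 6 melanocyte markers 1 fell (MITF, -0.43; adjusted p = 0.407), of 7 endothelial markers 1 rose (CDH5, 0.48; adjusted p = 0.538) and of 7 neural markers 1 rose (MAP2, 0.24; adjusted p = 0.635). Of 11 immune markers CD14 rose by 0.54, HLA-DRA by 0.40 and HLA-DRB1 by 0.22, and CD1A fell by 0.30 (list adjusted p = 0.297). Adjusted over the list alone the counts were the same for fibroblast, melanocyte, endothelial and neural markers, and 5 immune markers rose and 2 fell. The call of MAP2, which has 1 of 3 probe sets called in the opposite direction, was lost in the mean of its probe sets (0.020, adjusted p = 0.761). DCN, HLA-DRB1 and MAP2 turned to -0.064, -0.091 and -0.075 at equal poly-A spikes. The calls of DCN (without empty vector replicate 1 or 3), HLA-DRB1 (without G130V replicate 1) and CD1A (without empty vector replicate 1 or 3, or G130V replicate 1 or 3) were each lost, with adjusted p from 0.0515 to 0.0735, and without empty vector replicate 3 a single fibroblast marker fell.

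**Figure D3:**
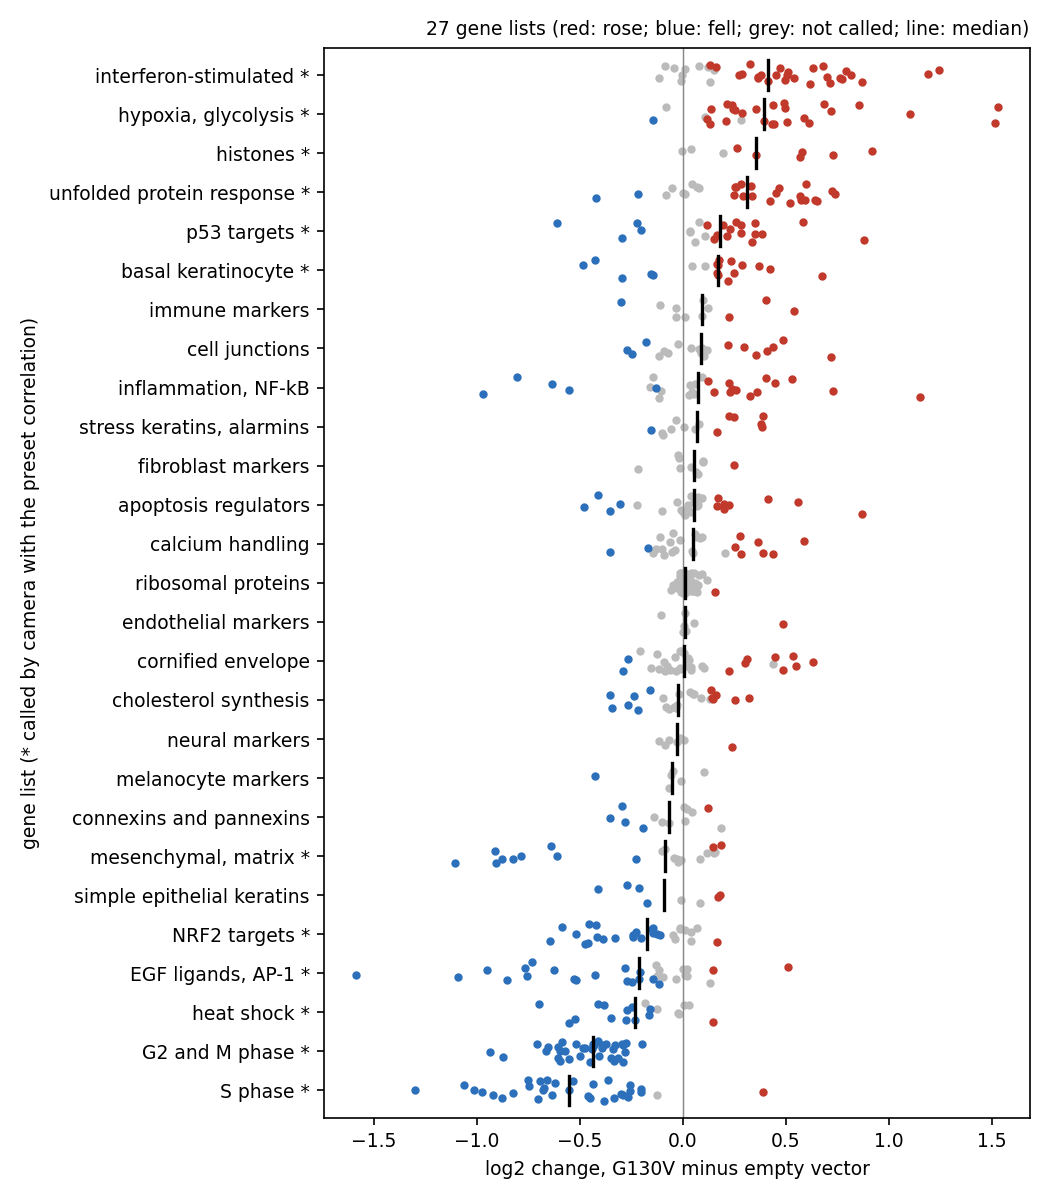
Log2 change (G130V minus empty vector) of every measured member of the 27 gene lists, ordered by the list median (black line), with called members in red (rose) or blue (fell) and an asterisk at lists called by camera with the preset correlation. The S phase list has the lowest median, -0.55, and the interferon list the highest, 0.42; at equal poly-A spikes every value moves down by 0.31, which turns the medians of the p53, basal keratinocyte and all lower lists above 0 to below 0.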

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

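Of the tests in this part, those on RNA degradation, on the amount of RNA and on separate preparation were chosen after the result was seen.

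The poly-A spike controls, which no comparison of the report uses as a result, read 0.31 higher (log2) on the G130V arrays, with all 24 probe sets higher, by 0.20 to 0.45. The hybridisation controls, which are added after labelling, differed by 0.074. Among 1750 probe sets with several gene symbols or none, which were left out of the gene comparison, 451 were called (25.8%), with 249 higher and 202 lower in G130V cells.

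The broad change between the groups, 4772 called genes, was set against technical explanations. Only 1 of the 10 ways to split the 6 arrays into 3 and 3 gave as many, the real one, and the highest of the others gave 0, but 10 splits are too few for a share under 0.05. Degraded RNA in 1 group is argued against by the difference between 3′ and 5′ control probe sets, which shifted by 2.33e-04 (log2, 95% interval -0.070 to 0.071). A different amount of RNA per spike that acts on all genes alike was set against the 27 lists fixed before the data were examined. In 13 lists the 95% bootstrap interval of the median left out the median change of all genes, 7 above it and 6 below. Chance gives up to 4 where members vary independently, but the bootstrap drew genes and not arrays. Normalization between arrays also takes out any shift shared by all genes. Such a shift therefore cannot be judged from these lists, which show only that changes differed between lists. Separate preparation of the groups stays open, since the spike shift of 0.31 (interval 0.20 to 0.43) follows the groups and no label gives a batch, so that preparation and virus cannot be told apart.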

How the results depend on the processing

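The trend prior and the shift to equal poly-A spikes were chosen after the data were seen. Of 102 named genes other than GJB2 and FLG, 95 kept direction and call in every alternative that tested them except the spike shift (the filters left out 1 and 24), and none reversed, while under that shift 11 lost the call and 6 reversed. RPS9, DCN, CD1A, HLA-DRB1, GJA1, CFLAR and MAP2 each lost the call in at least 1. Leaving out an array gave 3527 to 4293 called genes (1891 to 2288 rose, 1636 to 2054 fell), GJB2 from -0.42 to -0.29, FLG from 0.44 to 0.55, and 11 to 13 lists. Over those fits the basal keratinocyte mean ran from 0.089 to 0.12 with 1 call lost, and the junction mean from 0.11 to 0.14 with 1 gained. The same-numbered arrays did not deviate together (correlations -0.024, -0.0025 and -0.075). These values gave no sign of pairing, but they cannot rule out that same-numbered samples were handled together. With the replicate block 4158 genes were called (2237 rose, 1921 fell), GJB2 changed by -0.35 and FLG by 0.49, and 12 lists were called, while RPS9 and GJB2 probe set 11748025_s_at were not.

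Testing every probe set on its own called 10833 (5518 rose, 5315 fell), more probe sets being tested. Stricter thresholds call fewer by construction: 2886 at an adjusted p under 0.01 (1495 and 1391), 328 at 1.5-fold (166 and 162) and 44 at 2-fold (25 and 19). In the mean of its probe sets, which differ in sign, GJB2 changed by -0.13 (adjusted p = 0.0857, against 0.00674 to 0.0352 on leaving out arrays). At equal poly-A spikes 13436 genes were called (352 rose, 13084 fell) and FLG changed by 0.18. Values that reversed there, by construction since all values drop by 0.31, were S100A9 (-0.064), KRT13 (-0.13), RPS9 (-0.16), DCN (-0.064), HLA-DRB1 (-0.091), MAP2 (-0.075) and GJB2 probe set 11748025_s_at (-0.17).

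With an estimated correlation 0 lists were called, the means being unchanged at 0.10 (basal), 0.16 (p53), 0.30 (unfolded protein response), 0.42 (interferon), -0.55 (S phase), -0.47 (G2 and M), -0.30 (mesenchymal), 0.45 (hypoxia), -0.22 (NRF2), -0.33 (EGF and AP-1), -0.23 (heat shock) and 0.40 (histones). The estimated correlations, 0.017 to 0.38 for these lists, and the 4 residual degrees of freedom camera then uses widen the test. Fry, which tests another hypothesis, called 24, adding -0.081 (connexins), 0.080 (cornified envelope), 0.11 (stress keratins), -0.081 (simple keratins), 0.12 (junctions), 0.052 (apoptosis), 0.066 (NF-kB), 0.072 (calcium), 0.020 (ribosomal), -0.085 (melanocyte), 0.091 (immune) and 0.065 (endothelial). With the dimmer 50% of genes left out the basal (0.10) and mesenchymal (-0.29) calls were lost, with fewer genes tested; with quantile normalization the junction list (0.14) was called, and the cause was not tested. Camera on ranks changed no list's call. Restricting to the filtered annotated table changes nothing, since it lists the same probe sets; its own sample columns could not be matched, and no linear values called for a pseudocount.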

Other observations

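The Gene Ontology terms, all tests below and the genes given as examples were chosen after the result was seen, the test of YAP and TAZ targets before its own values were.

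Beyond the fixed lists, more genes of mitochondrial protein synthesis fell than rose in G130V cells. Of 85 genes annotated to mitochondrial translational elongation, none of which is in a fixed list, 42 fell, 5 rose and 38 did not pass, with a median of -0.12 (camera adjusted p = 1.61e-06 over 936 terms, and adjusted p = 0.949 with an estimated correlation). The mitochondrial ribosomal protein genes MRPL39, MRPL24 and MRPL3 fell by 0.37, 0.32 and 0.31. Of the genes of RNA processing and transport that passed, most fell. Of 113 rRNA processing genes, 12 of them in fixed lists, 46 fell, 4 rose and 63 did not pass (median -0.11, adjusted p = 1.03e-06), with the exosome subunit gene EXOSC2 and the ribosome assembly factor gene EMG1 each falling by 0.45. Of 86 mRNA transport genes 38 fell, 2 rose and 46 did not pass (median -0.082, adjusted p = 1.01e-05), among them the nuclear pore gene NUP155, which fell by 0.48, and ALYREF, an mRNA export adaptor, which fell by 0.47. Of 125 tRNA processing genes 48 fell, 6 rose and 71 did not pass (median -0.075, adjusted p = 1.04e-04), but 24 of these genes and 13 of the falls are shared with mRNA transport. The estimated correlation gave an adjusted p of 0.949 for each of these terms too.

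In terms of the secretory pathway and of intraciliary transport more genes rose than fell, with small medians that all lie below 0 at equal poly-A spikes, where every value drops by 0.31. Of 31 protein secretion genes 11 rose and 20 did not pass (median 0.059, adjusted p = 0.0179, and adjusted p = 0.949 with an estimated correlation, as for the other terms below), led by RAB26, a GTPase of secretory granules, at 0.93. Of 166 N-linked glycosylation genes, 6 of them in fixed lists, 52 rose, 19 fell and 95 did not pass (adjusted p = 0.0404). Of 45 genes of degradation from the endoplasmic reticulum, 5 of them in fixed lists, 15 rose, 6 fell and 24 did not pass (adjusted p = 0.0432), and 12 of these genes and 6 of the rises are shared with N-linked glycosylation. Of 18 intraciliary transport genes 8 rose and 10 did not pass (median 0.16, adjusted p = 0.0417), among them IFT70A at 0.65 and BBS12 at 0.52. The last 3 terms lost their call on leaving out single arrays, with adjusted p up to 0.0743, 0.0709 and 0.0882, without empty vector replicate 1 or G130V replicate 3 for all 3. In all 92 terms were called, 15 upward and 77 downward, from 82 to 106 on leaving out an array, and 0 with an estimated correlation (camera).

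GJB2 transcript was not clearly raised in cells that received a GJB2 virus. A candidate explanation is that a vector holding only the coding sequence is seen by the probe set aligned to that sequence and not by the other 2. That assumes that the other 2 read other parts of the transcript. Their aligned span includes that of the coding sequence probe set, and probe positions are not given in the sources used here. The coding sequence probe set changed by 0.42 more than the mean of the other 2 (log2, 95% interval 0.19 to 0.64). The shift to equal poly-A spikes leaves that difference unchanged. Its own rise of 0.14 (0.11 to 0.17 on leaving out single arrays) was only 1.10-fold and turned to -0.17 at equal poly-A spikes. All 3 probe sets lie at a low level, where values may be close to background, so the explanation stays open. Exchanged group labels could also give a lower GJB2 level in the arrays labelled G130V. The value of 0.14 does not decide this, since its sign depends on that shift. The difference of 0.42 does not depend on the shift, but it rests on the same dim probe sets and does not decide it either. That the sign must hold at equal poly-A spikes was required of both tests only after the values were seen, and without it the first would favour the coding sequence and the second would argue against an exchange.

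Fewer cell cycle transcripts and more hypoxia transcripts in the G130V arrays may come from denser cultures. Targets of YAP and TAZ, which fall in dense cultures, were chosen without genes whose values had been seen, and 11 of 22 measured fell and 3 rose, with a median of -0.13 (95% bootstrap interval -0.17 to -0.027), AXL falling by 0.70 and F3 by 0.50 but NT5E rising by 0.42 and IGFBP3 by 0.26 (camera p = 8.62e-04, and p = 0.0561 with an estimated correlation). Admixed fibroblasts are argued against by the 10 measured fibroblast markers, with a median of 0.052 (interval -0.019 to 0.099). A virus dose or passage that differs between the groups cannot be told apart from the G130V change, since the interferon-stimulated genes differ (median 0.42) but each group had its own virus and no label gives a dose. An effect of the G130V protein itself stays among the open explanations, untested by this design. No sample was given GJB2 without G130V, so an effect of the mutation could not be told apart from one of added GJB2.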
